A study of Mus musculus with 12 samples.

How the data were processed

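Poly-A RNA of cardiomyocytes isolated from mouse hearts was sequenced in 12 libraries, 3 in each of 4 groups: mdx with saline, mdx with PB1046, mdx:Utrn+/- with saline and mdx:Utrn+/- with PB1046. Per the labels, animals received saline or PB1046 every other day from week 4 to week 12 and hearts were taken at week 14. The protocol names doses of 0.75 and 1.5 mg/kg, and the labels of the 6 PB1046 libraries name the high dose, taken here as 1.5 mg/kg. RNA came from frozen pellets of isolated cells with a RIN of at least 8, and 1.0 µg entered a stranded mRNA kit. The labels give no sex, collection hour or sequencing run, and their batch field repeats the group. Each library was taken as a mouse of its own, which the titles imply and the labels do not state. Groups were read from the labels, with replicate numbers as in the titles.

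The authors gave a single table of 18530 genes on mm10, deposited as tab-separated text and again with commas. Every cell of the copies was equal, and the first was used. The table is named as raw counts, but the deposited values per library are TPM: they are not whole, and every library sums to 1000000. The table also holds the authors' 6 pairwise group comparisons. Per the file headers these are a log2 fold change, an average log2 CPM, a likelihood ratio score, a p-value and a false discovery rate. By their correlation with the deposited TPM (r -0.993 to -0.999) the authors' log2 fold changes are the second named group minus the first. The submitters' processing notes name edgeR, with no version. The aligner, the read counter and the gene lengths are not given in the sources used here.

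Within a library the TPM of a gene is a whole number of reads times a step that depends on the gene's length and the library. These steps gave back whole reads, within a tolerance of 0.1 reads, for 100% of the values of 18530 genes. Libraries held 7234105 to 25458221 recovered reads. Recovered reads served limma-voom, depth and the read numbers behind scarce genes, and all other values rest on TPM. Gene symbols of 17407 genes (93.9%) matched the reference annotation. Start coordinates in the table are 0-based and are given here plus 1.

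Before the data were examined, the plan was a quasi-likelihood fit on counts. The deposited unit is TPM, so limma was used on it in its place, with the same groups, contrasts and thresholds, and reads recovered from TPM were given to limma-voom only. TPM were divided by a trimmed-mean factor (30% of log ratios and 5% of levels trimmed, factors 0.827 to 1.28) and put on the scale log2(TPM + 1). The 12798 genes with at least 1 TPM in at least 3 libraries were fitted with a mean per group on all 12 libraries (8 residual degrees of freedom) and moderated with trend and robust settings. There were 6 contrasts: PB1046 minus saline in each genotype, mdx:Utrn+/- minus mdx in each treatment, the difference of the PB1046 responses between genotypes, and their average. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Intervals are 95%. Without the scaling factors the median log2 change of all genes was 0.14 and 0.15 for PB1046 in mdx and mdx:Utrn+/- and -0.20 between genotypes under either treatment, against 0.01, -0.02, 0.03 and 0.00 with them.

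The gene lists, 33 in number, were fixed before the data were examined: NF-kB targets and components, cAMP-PKA-CREB components, CREB targets, the VIP system, the dystrophin-glycoprotein complex, extracellular matrix, cardiac stress, sarcomere, calcium handling, oxidative phosphorylation, fatty acid oxidation, glycolysis, interferon response, oxidative stress, the unfolded protein response, heat shock, clock, cell cycle, cell dissociation stress and sex-linked genes, and markers of macrophages, lymphocytes, neutrophils, endothelium, fibroblasts, smooth muscle and pericytes, erythroid cells, atrium, mesothelium, adipocytes, skeletal muscle and Schwann cells. Of these, 26 had at least 5 tested members. They were tested with limma camera at the preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated per list and with fry. To remove trends over gene length and abundance, each library's deviation from the gene's mean was fitted by lowess (span 0.3) over log2 length and then over the mean level, and the fits were taken off. A list score is the mean of the members' centred log2 values in a library. The relation of the macrophage and endothelial scores was tested with 10000 permutations of the libraries.

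The rule for named genes was also set in advance. It takes Dmd, Utrn, Vipr1 and Vipr2; per contrast the genes past the threshold with the largest change or, if none passes, the 5 per direction with the smallest unadjusted p, leaving out predicted genes; and up to 4 members per list with the smallest unadjusted p. The rule allows 802 pairs of gene and contrast, and 141 of these were picked for the text after their values were seen. Rn45s, Lars2, Trem2, Hba-a2, Hbb-bs, Npas2, Nr1d1 and Tmem181b-ps are named outside the rule, after their values were seen. The Y-linked gene Eif2s3y is named under this rule and was not called. All 12 libraries expressed the Y-linked gene Ddx3y (26.8 to 37.8 TPM by group) with Xist near 0, so no sex term was fitted.

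Single values were compared by exact permutation tests (two-sided, 400 relabelings within treatment or genotype), and correlations across libraries by 100000 permutations. Other splits of the libraries were counted, 10 for each pair of groups and 100 drawn for the other contrasts. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The steps were tested on simulated data built from the recovered reads, with 50 changed genes per fold in each of 5 runs. At 3 against 3 libraries, 25.2% of genes changed 2-fold, 73.6% of those changed 4-fold, 88% of those changed 8-fold and 93.2% of those changed 16-fold were recovered, with 9.6 false calls among 149.6 calls per run. In the real data the median standard error of a log2 change between a pair of groups was 0.255.

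Alternatives planned in advance were median-of-ratios and upper-quartile scaling, limma-voom on recovered reads, a stricter filter, no filter, a pseudocount of 0.5, genes with an average log2 level of at least 3, a threshold of 0.1, only the groups of a contrast, a replicate block, a term for the 3 lowest library numbers, an estimated correlation in camera, and leaving out each library. Chosen after the data were seen were TPM without scaling, a pseudocount of 0.1, library weights, terms for log2 Rn45s, for the endothelial marker score and for the first component of the residuals, and a fit without microRNA, small nucleolar RNA, Rn45s and Lars2.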

Results

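Cardiomyocytes isolated from hearts of dystrophin-deficient mdx mice, and of mdx mice with a single working copy of Utrn (mdx:Utrn+/-), were compared after saline or PB1046, a sustained-release analog of vasoactive intestinal peptide (VIP). The series names transcripts of cAMP-PKA-CREB and NF-kB signaling as its subject. Each of the 4 groups held 3 libraries, and values are mean ± SD in TPM (transcripts scaled by gene length and library total) unless another quantity is named.

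Utrn, the autosomal homolog of dystrophin, followed the genotype labels on average. It was 9.82 ± 1.29 TPM in mdx saline and 4.97 ± 1.51 TPM in mdx:Utrn+/- saline (n = 3 each, 49.4% lower). Under PB1046 it was 13.8 ± 6.71 TPM in mdx and 6.84 ± 2.82 TPM in mdx:Utrn+/- (n = 3 each, 50.6% lower). Utrn lies at chr10:12382188 to 12861735 (mm10, 1-based). Averaged over treatments the genotype difference was -0.64 on the log2 scale. A two-sided exact permutation test that exchanged genotypes within each treatment gave p = 0.02 over 400 relabelings, where 0.005 is the smallest p possible. In limma across all genes Utrn did not pass (adjusted p = 0.837 under saline, 1 under PB1046). PB1046 minus saline for Utrn was 0.18 in mdx and 0.20 in mdx:Utrn+/- (log2), within the spread between replicates. Dmd, the dystrophin gene, whose mdx allele is transcribed despite a premature stop codon, was 4.20 ± 0.84, 3.98 ± 0.69, 3.37 ± 1.802 and 3.25 ± 0.57 TPM in mdx saline, mdx PB1046, mdx:Utrn+/- saline and mdx:Utrn+/- PB1046. Its log2 differences, -0.18 and -0.09 with PB1046 in mdx and mdx:Utrn+/-, and -0.14 and -0.05 between genotypes under saline and PB1046, were within the spread between replicates.

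Transcripts of the VIP receptors were scarce in all 4 groups. Vipr1 ranged from 0.163 ± 0.0316 TPM in mdx saline to 0.593 ± 0.444 TPM in mdx PB1046, on 3 to 38 reads per library. Vipr2 ranged from 0.160 ± 0.0355 TPM in mdx:Utrn+/- saline to 0.271 ± 0.109 TPM in mdx saline, on 2 to 15 reads. Both lay under the 1 TPM filter, so the main fit did not test them. In a fit without that filter Vipr1 did not pass for PB1046 in mdx (log2 change 0.32, 95% interval -0.07 to 0.70, adjusted p = 1), nor did Vipr2 (-0.07, -0.27 to 0.13). The authors' own result file gives Vipr1 a log2 change of 1.56 in mdx with a p-value of 0.0324 and an adjusted p of 1, and Vipr2 -0.23 with an adjusted p of 1. Adcyap1r1, the receptor gene that prefers the related peptide PACAP, was 2.23 ± 1.05 TPM in mdx saline and 6.61 ± 0.92 TPM in mdx PB1046 (n = 3 each). In mdx:Utrn+/- it was 4.93 ± 3.65 TPM in saline and 3.75 ± 2.04 TPM in PB1046. It did not pass in limma (log2 change in mdx 1.15, 95% interval -0.08 to 2.39). Across the 12 libraries Adcyap1r1 followed the ribosomal precursor entry Rn45s (Pearson r = 0.93, permutation p = 4e-05, Spearman rho = 0.90, permutation p = 0.00023). The adjusted p was 6e-05 over the 3 relations computed. The r was 0.92 without the 2 libraries farthest from the median of Rn45s, and 0.92 after the group means were taken out. With log2 Rn45s as a term the log2 change of Adcyap1r1 in mdx was 0.33. Of the VIP system list (VIP, PACAP, their receptors and receptor activity-modifying proteins) 4 of 8 genes were measurable, too few for a list test. They had median log2 changes of 0.47 in mdx and -0.02 in mdx:Utrn+/-.

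**Figure D1:**
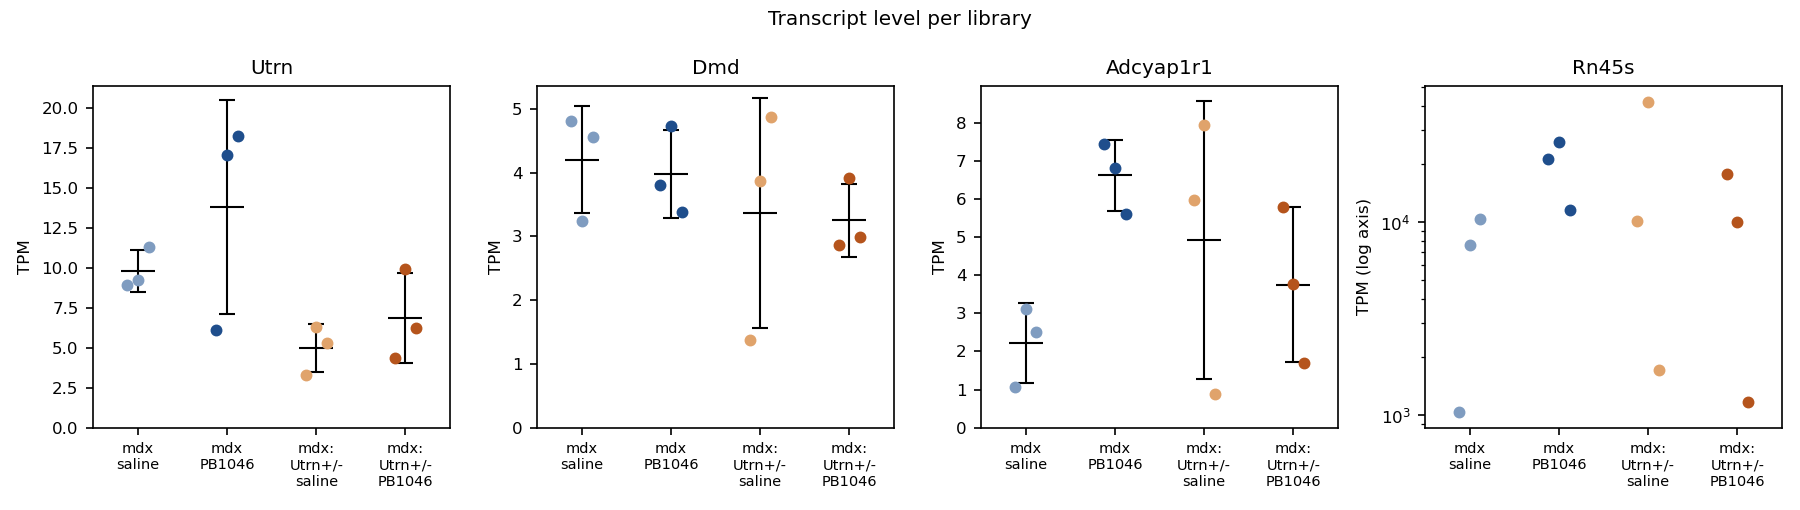
Transcript level (TPM, y axis) of Utrn, Dmd, Adcyap1r1 and Rn45s in each library (points) of the 4 groups (x axis), with black bars for mean ± SD of 3 libraries and a log axis with points alone for Rn45s. Utrn was 9.82 and 4.97 TPM in mdx and mdx:Utrn+/- under saline, and Rn45s ran from 1039 TPM in mdx saline replicate 1 to 42106 TPM in mdx:Utrn+/- saline replicate 2.

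The libraries also differed in ways that the groups did not follow. The first principal component held 30.9% of the variance and set 5 libraries (mdx saline replicates 2 and 3, mdx PB1046 replicates 2 and 3, and mdx:Utrn+/- PB1046 replicate 2) apart from the other 7. Thus mdx:Utrn+/- saline had no library on the first side. The mdx libraries among the 5 carried the highest library numbers of the series, above those of every mdx:Utrn+/- library. What these numbers stand for is not given, so their order cannot be fully parted from genotype there. The term for the 3 lowest library numbers does not follow this split. Only 21.5% of this component lay between groups. The endothelial marker score (mean centred log2 level) was 0.30 to 1.15 in the 5 libraries and -0.92 to -0.10 in the 7. Interferon response genes were 0.20 to 0.52 against -0.55 to -0.13, and NF-kB pathway components 0.02 to 0.20 against -0.15 to -0.03. Glycolysis genes, -0.45 to -0.15 in the 5 and 0.15 to 0.39 in the 7, and cardiomyocyte sarcomere genes, -0.61 to -0.04 against 0.08 to 0.36, ran the other way. The second component held 21.8% of the variance. Among the genes with the largest positive weights on it were the globin genes Hba-a1, Hba-a2 and Hbb-bs, Rn45s and the macrophage genes Spp1 and Trem2.

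**Figure D2:**
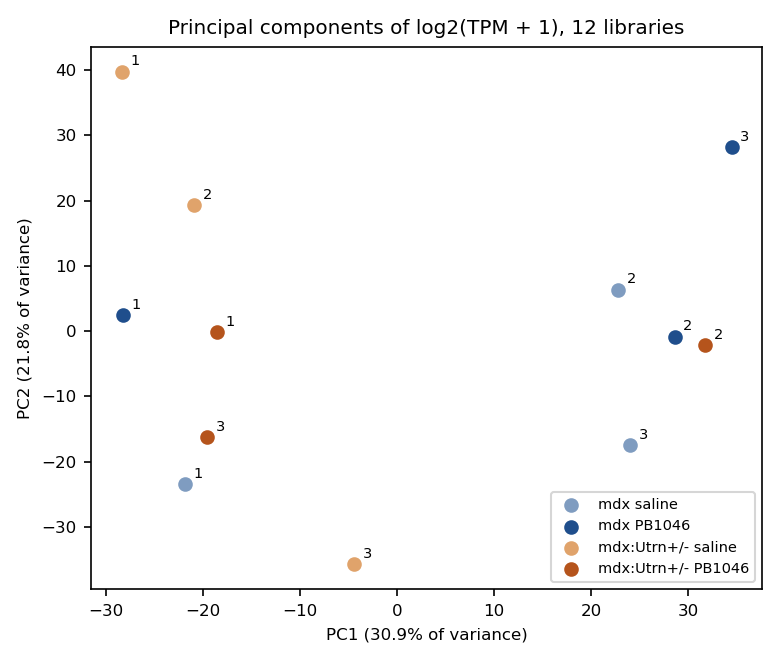
Positions of the 12 libraries (points, coloured by group, with replicate numbers) on the first (x axis) and second (y axis) principal components of log2(TPM + 1), which held 30.9% and 21.8% of the variance. The 5 libraries to the right of 0 on the first component come from 3 of the 4 groups.

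NF-kB target genes were higher with PB1046 than with saline in the mdx libraries: 22 of 26 measured members were higher, with a median log2 change of 0.38. Ccl2, a chemokine that recruits monocytes, was 14.6 ± 6.71 TPM in saline and 67.8 ± 11.3 TPM in PB1046 (n = 3 each, log2 change 2.09). The adhesion molecules Icam1 (10.3 ± 3.97 and 23.1 ± 10.6 TPM, log2 0.89) and Sele (0.666 ± 0.057 and 2.54 ± 1.797 TPM, log2 0.84) stood on the same side. So did the prostaglandin synthase Ptgs2 (1.56 ± 0.327 and 4.20 ± 0.579 TPM, log2 0.90). The list rose by camera at its preset correlation (adjusted p = 1.29e-05), which an estimated correlation did not uphold (adjusted p = 0.743). The same libraries also differed in depth and in Rn45s. Each mdx PB1046 library held fewer reads (11468022 to 14182394) than each mdx saline library (18162966 to 25458221), and Rn45s was 6351 ± 4807 TPM in saline and 19574 ± 7298 TPM in PB1046. With log2 Rn45s as a term, an alternative chosen after the data were seen, the adjusted p of the NF-kB target list was 0.0396. Over the 12 libraries its score had a Pearson r of 0.78 with the second principal component, on which Rn45s, globin and macrophage genes had large weights. Among NF-kB pathway components 17 of 26 were higher (median log2 0.10, adjusted p = 0.167). The Toll-like receptor adaptor Myd88 was 12.5 ± 1.36 and 21.8 ± 5.94 TPM.

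The cAMP-PKA-CREB pathway components also rose at the preset correlation in mdx: 23 of 30 were higher, median log2 0.15 (adjusted p = 0.0301, and adjusted p = 0.743 with an estimated correlation). The cAMP phosphodiesterase Pde3a was 1.96 ± 0.577 and 5.26 ± 1.25 TPM (log2 0.95). The PKA regulatory subunit Prkar2a was 13.3 ± 2.46 and 26.8 ± 9.88 TPM (log2 0.77), and the PKA anchor Akap12 was 10.6 ± 4.34 and 34.8 ± 27.4 TPM (log2 1.09). This call ended without mdx saline replicate 2 (adjusted p = 0.154) or mdx PB1046 replicate 2 (adjusted p = 0.164). Its adjusted p ran from 0.0210 to 0.164 over the 12 refits that left out a library. The call also ended with log2 Rn45s as a term (adjusted p = 0.0614). CREB target genes leaned lower, 13 of 22 with median log2 -0.25, and did not pass (adjusted p = 0.0883). The immediate early gene Fos was 163 ± 47.4 and 86.8 ± 4.31 TPM (log2 -1.01). Junb was 157 ± 38.5 and 105 ± 28.6 TPM, and Egr1 was 96.2 ± 22.7 and 61.5 ± 37.8 TPM. These 3 genes are also members of the cell dissociation stress list (10 of 16 lower, median log2 -0.25, adjusted p = 0.0510).

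Oxidative phosphorylation genes fell in mdx with PB1046 at the preset correlation, 28 of 31 lower with a median log2 change of -0.40 (adjusted p = 2.66e-09, but 0.743 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, was 4159 ± 195 and 3020 ± 333 TPM (log2 -0.62). Atp5o, of ATP synthase, was 4459 ± 814 and 3310 ± 346 TPM (log2 -0.57). All 16 cardiomyocyte sarcomere genes were lower (median log2 -0.29, adjusted p = 0.000321). With the trends of the log2 values over gene length and abundance removed the sarcomere call ended (median log2 -0.03, 9 of 16 lower, adjusted p = 0.513). The cardiac troponin Tnni3 was 17096 ± 3412 and 13360 ± 1773 TPM. Glycolysis genes were lower in 16 of 18 (median log2 -0.14, adjusted p = 0.0102). This call ended with the trends removed (median log2 -0.11, adjusted p = 0.127) and with the Rn45s term (0.0614). It also ended without mdx saline replicate 1 (0.491) or mdx PB1046 replicate 2 (0.110) or 3 (0.343). The muscle enolase Eno3 was 2251 ± 121 and 1688 ± 99.8 TPM. Fatty acid oxidation genes were higher in 24 of 30 (median log2 0.19, adjusted p = 0.0425). Pdk4, the kinase that turns off pyruvate dehydrogenase, was 68.7 ± 71.7 and 233 ± 115 TPM (log2 1.93). The adjusted p with an estimated correlation was 0.743, 0.764 and 0.866 for these 3 lists. With the trends removed the oxidative phosphorylation median was -0.12 (adjusted p = 0.0174, but 0.754 with an estimated correlation). The list score was -0.51 and -0.64 in mdx PB1046 replicates 2 and 3 but 0.16 in replicate 1, within saline (-0.15 to 0.25). The fatty acid oxidation list turned downward without mdx saline replicate 2 (0.858) or mdx PB1046 replicate 1 (0.329), and its call ended without mdx saline replicate 3 (0.217, range 5.34e-06 to 0.858). The sarcomere call ended without mdx PB1046 replicate 3 (adjusted p = 0.235, range 1.68e-07 to 0.235). Across genes the log2 change went with transcript length (rho 0.14), and oxidative phosphorylation genes have a median length of 1073 bases against 2790 for all genes tested.

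Extracellular matrix genes rose in mdx at the preset correlation, 25 of 31 higher with a median log2 change of 0.46 (adjusted p = 0.000144, and adjusted p = 0.743 with an estimated correlation). The matricellular gene Thbs1 was 12.6 ± 6.03 and 52.9 ± 9.76 TPM (log2 1.94), and Spp1, osteopontin, was 20.01 ± 11.4 and 70.7 ± 15.98 TPM (log2 1.77). Markers of other cell types moved with them. Fibroblast markers were higher in 12 of 14 (median log2 0.47, adjusted p = 0.00318). Pdgfra was 4.04 ± 1.78 and 10.9 ± 1.45 TPM. Smooth muscle and pericyte markers were higher in 8 of 9 (0.46, adjusted p = 0.00437). Rgs5 was 38.4 ± 21.2 and 100.4 ± 52.0 TPM. Macrophage markers were higher in 17 of 18 (0.42, adjusted p = 0.0413), and erythroid markers in 5 of 5 (1.93, adjusted p = 0.000321). The globin Hba-a1 was 9.19 ± 6.45 and 79.5 ± 103 TPM. Endothelial markers were level (8 of 15 higher, median 0.00, adjusted p = 0.909). The adjusted p with an estimated correlation was 0.860 for macrophage markers and 0.743 for the other called marker lists. Without mdx saline replicate 3 the extracellular matrix call ended (adjusted p = 0.399), as did the fibroblast call (0.156), and the macrophage list turned downward (0.868). Without mdx PB1046 replicate 3 the fibroblast (0.755), macrophage (0.775), smooth muscle (0.235) and erythroid (0.0808) calls ended. Without mdx saline replicate 1 the fibroblast (0.118), macrophage (0.502) and smooth muscle (0.0904) calls ended, and without mdx PB1046 replicate 1 the macrophage call (0.0701). With log2 Rn45s as a term the adjusted p was 0.229 for extracellular matrix, 0.0614 for fibroblast and macrophage and 0.307 for smooth muscle and pericyte lists. The macrophage call also ended with the endothelial score as a term (0.0941). Over the 12 refits the adjusted p of the extracellular matrix, fibroblast and macrophage lists ran from 2.55e-14 to 0.399, 5.51e-08 to 0.755 and 3.84e-09 to 0.868.

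The clock list fell in mdx, 12 of 16 lower with a median log2 change of -0.32 (adjusted p = 0.0425, and adjusted p = 0.743 with an estimated correlation). It did not pass with the Rn45s term (0.228) or the endothelial score as a term (0.0628), nor without mdx saline replicate 3 (0.217), mdx PB1046 replicate 1 (0.163) or 2 (0.537) or mdx:Utrn+/- PB1046 replicate 2 (0.0553). The output gene Dbp was 143 ± 45.5 and 82.3 ± 76.5 TPM. The lists that did not pass were calcium handling (15 of 21 lower, median -0.14), oxidative stress (13 of 18 higher, 0.17), cell cycle (12 of 16 lower, -0.11) and heat shock (8 of 10 higher, 0.15). Others were mesothelial markers (0.05), the unfolded protein response (0.11), interferon response (-0.02), atrial markers (-0.05), cardiac stress genes (-0.02) and the dystrophin-glycoprotein complex (-0.03). Median, mean and test differed in sign for the last 4. Genes outside these lists with the smallest unadjusted p on the higher side were Inhbb, an activin subunit (0.721 ± 0.177 and 3.36 ± 0.888 TPM, log2 1.19), and the metalloproteinase Mmp3 (1.85 ± 0.928 and 8.07 ± 0.468 TPM, log2 1.58). Next came Spata5l1 (log2 0.74), the sphingomyelin synthase Sgms1 (10.01 ± 1.78 and 19.2 ± 3.60 TPM, log2 0.72) and Dnajc27 (log2 0.70). On the lower side were the small GTPase Rrad, a calcium channel regulator (311 ± 90.5 and 139 ± 10.1 TPM, log2 -1.28), and Ky (8.77 ± 2.52 and 3.39 ± 0.774 TPM, log2 -1.25). Mir7091 (log2 -1.19) and Pus10 (log2 -0.64) followed. Mir186 also stood there, but rested on 1 to 3 reads per library in saline and was listed at 0 in PB1046.

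No gene passed an adjusted p of 0.05 for PB1046 in mdx, by limma on 12798 genes or by limma-voom on recovered reads (0 genes each). At an unadjusted p under 0.05 limma had 396 genes (238 higher, 158 lower) and limma-voom 446. Uniform p would give 640, and other splits had a median of 481 by limma. The smallest adjusted p was 0.409, and counts adjusted over the list alone were 0 for all 33 lists. At the preset correlation 12 of 26 lists were called (8 up, 4 down), with an estimated correlation 0, and by fry 0. Of the 12 calls 2 (oxidative phosphorylation and NF-kB target genes) held in all 12 refits that left out a library and 10 ended at least once.

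Endothelial markers rose with PB1046 in mdx:Utrn+/- at the preset correlation, 15 of 15 higher with a median log2 change of 0.56 (adjusted p = 6.31e-05, and adjusted p = 0.812 with an estimated correlation). The tight junction gene Cldn5 was 13.4 ± 4.73 TPM in saline and 45.8 ± 26.1 TPM in PB1046 (n = 3 each, log2 1.41). The VEGF receptor Kdr was 15.5 ± 1.89 and 52.1 ± 44.1 TPM. Macrophage markers fell, 18 of 18 lower with median log2 -0.53 (adjusted p = 0.00211, and adjusted p = 0.812 with an estimated correlation). The leukocyte phosphatase Ptprc was 3.85 ± 1.40 and 2.13 ± 0.729 TPM, the LPS co-receptor Cd14 9.64 ± 4.31 and 5.46 ± 0.995 TPM, and the scavenger receptor Cd163 2.08 ± 1.02 and 1.02 ± 0.119 TPM. Extracellular matrix genes fell as well, 28 of 31 lower with median log2 -0.38 (adjusted p = 0.0125, and adjusted p = 0.812 with an estimated correlation). Ctgf was 169 ± 73.4 and 101 ± 39.5 TPM and Cthrc1 4.02 ± 1.24 and 1.66 ± 0.887 TPM. The endothelial call ended without mdx:Utrn+/- PB1046 replicate 2 (adjusted p = 0.231, range over the 12 refits 4.75e-07 to 0.231), which had the only score of its group among the 5 high endothelial scores. The macrophage list turned upward without mdx:Utrn+/- saline replicate 1 (0.474), and its call ended without mdx:Utrn+/- PB1046 replicate 1 (0.0681, range 1.32e-05 to 0.474). The extracellular matrix call ended without mdx:Utrn+/- saline replicate 1 (0.374) or 2 (0.352) or PB1046 replicate 3 (0.407, range 2.39e-05 to 0.407), and with the endothelial score as a term (median -0.31, adjusted p = 0.126).

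Core clock genes stood on both sides in mdx:Utrn+/-, none of them past its test. The activators Arntl (0.990 ± 0.296 and 7.15 ± 5.23 TPM, log2 1.66) and Clock (3.65 ± 0.886 and 7.92 ± 3.15 TPM, log2 0.74) were higher with PB1046. The repressor Cry2 (16.2 ± 0.137 and 10.5 ± 0.660 TPM, log2 -0.77) and the output gene Tef (122 ± 42.0 and 70.6 ± 12.3 TPM, log2 -0.94) were lower. The activator Npas2 (1.09 ± 0.861 and 1.07 ± 0.451 TPM) was level and the repressor Nr1d1 (10.6 ± 4.87 and 23.7 ± 15.7 TPM) stood with the activators. As a list the clock fell, 13 of 16 lower with median log2 -0.49 (adjusted p = 0.00304, and adjusted p = 0.812 with an estimated correlation). It had 9 members at an unadjusted p under 0.05, 0 adjusted over all genes and 0 adjusted over the list alone. The call ended without mdx:Utrn+/- saline replicate 3 (adjusted p = 0.312, range 7.96e-08 to 0.312). Collection hour is not given in the sources used here. Glycolysis genes fell (13 of 18 lower, median -0.22, adjusted p = 0.0183, and adjusted p = 0.812 with an estimated correlation). The glucose transporter Slc2a1 was 14.4 ± 2.29 and 9.66 ± 3.69 TPM and hexokinase Hk2 103 ± 3.72 and 81.4 ± 13.9 TPM. The glycolysis call ended without mdx:Utrn+/- saline replicate 1 (0.108) or PB1046 replicate 2 (0.887, range 0.00245 to 0.887). It also ended with the length and abundance trends removed (median -0.10, adjusted p = 0.0747) and with the endothelial score as a term (median 0.02, 8 of 18 lower, adjusted p = 0.859).

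The pathways that the series names showed no list call in mdx:Utrn+/-. NF-kB target genes were lower in 17 of 26 (median log2 -0.10, adjusted p = 0.782), with Traf1 at 1.73 ± 0.697 and 0.965 ± 0.956 TPM and the cytokine Il1b at 3.96 ± 1.08 and 3.00 ± 1.56 TPM. NF-kB pathway components were lower in 14 of 26 (-0.01, adjusted p = 0.508), with the receptor Tlr2 at 3.29 ± 1.90 and 1.72 ± 0.514 TPM. The cAMP-PKA-CREB components were split, 15 higher and 15 lower (adjusted p = 0.398). Creb1 was 3.51 ± 0.403 and 5.59 ± 2.38 TPM and the phosphodiesterase Pde3b 1.37 ± 0.0552 and 1.18 ± 0.243 TPM. CREB target genes had a median of -0.07 (14 of 22 lower, adjusted p = 0.946). The clock gene Per2 was 16.97 ± 17.7 and 6.11 ± 3.36 TPM and Egr1 29.8 ± 4.08 and 73.4 ± 42.5 TPM. Sarcomere (14 of 16 lower, median -0.15), cell cycle (14 of 16), calcium handling (18 of 21), atrial (7 of 7) and oxidative stress genes (14 of 18) shared an adjusted p of 0.0740. The titin cap Tcap was 15419 ± 6500 and 7946 ± 4376 TPM and Nqo1, a quinone reductase, 79.8 ± 8.14 and 54.9 ± 6.999 TPM. The remaining lists gave medians of 0.69 (erythroid), 0.26 (mesothelial), -0.32 (cardiac stress), 0.10 (interferon response), 0.14 (cell dissociation stress) and -0.12 (dystrophin-glycoprotein complex). In the last, the membrane repair gene Dysf was 18.5 ± 4.43 and 31.2 ± 9.63 TPM. Medians were -0.11 (oxidative phosphorylation), -0.20 (fibroblast), -0.04 (unfolded protein response), 0.03 (fatty acid oxidation), -0.01 (heat shock) and -0.09 (smooth muscle and pericyte). The test pointed up where the median was negative for cAMP-PKA-CREB components, NF-kB pathway components, heat shock, smooth muscle and CREB targets. The mean also differed in sign from the median in the first pair.

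No gene passed for PB1046 in mdx:Utrn+/- by limma or limma-voom (0 genes each, smallest adjusted p 0.997). At an unadjusted p under 0.05 limma had 264 genes (107 higher, 157 lower) and limma-voom 218. Uniform p would give 640, and other splits had a median of 324 by limma. The smallest unadjusted p on the higher side belonged to Zbtb12 (1.91 ± 0.0592 and 4.37 ± 0.550 TPM), the Hsp70 family member Hspa12a (4.39 ± 0.608 and 9.85 ± 2.35 TPM), the scaffold gene Grip2 (5.92 ± 2.70 and 21.3 ± 8.64 TPM), Snord49a and Mir7028. On the lower side were Slc25a29, a mitochondrial carrier (12.7 ± 2.05 and 6.64 ± 0.531 TPM), and C8g (5.11 ± 1.43 and 2.56 ± 0.463 TPM). Adamtsl4 (28.1 ± 4.56 and 18.9 ± 3.22 TPM), Crnde (8.96 ± 0.871 and 6.40 ± 1.10 TPM) and Snora23 followed. The small RNA entries rested on at most 5 reads per library in these groups. At the preset correlation 5 of 26 lists were called (1 up, 4 down), with an estimated correlation 0 and by fry 0, and none of the 5 calls held in all 12 refits that left out a library.

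**Figure D3:**
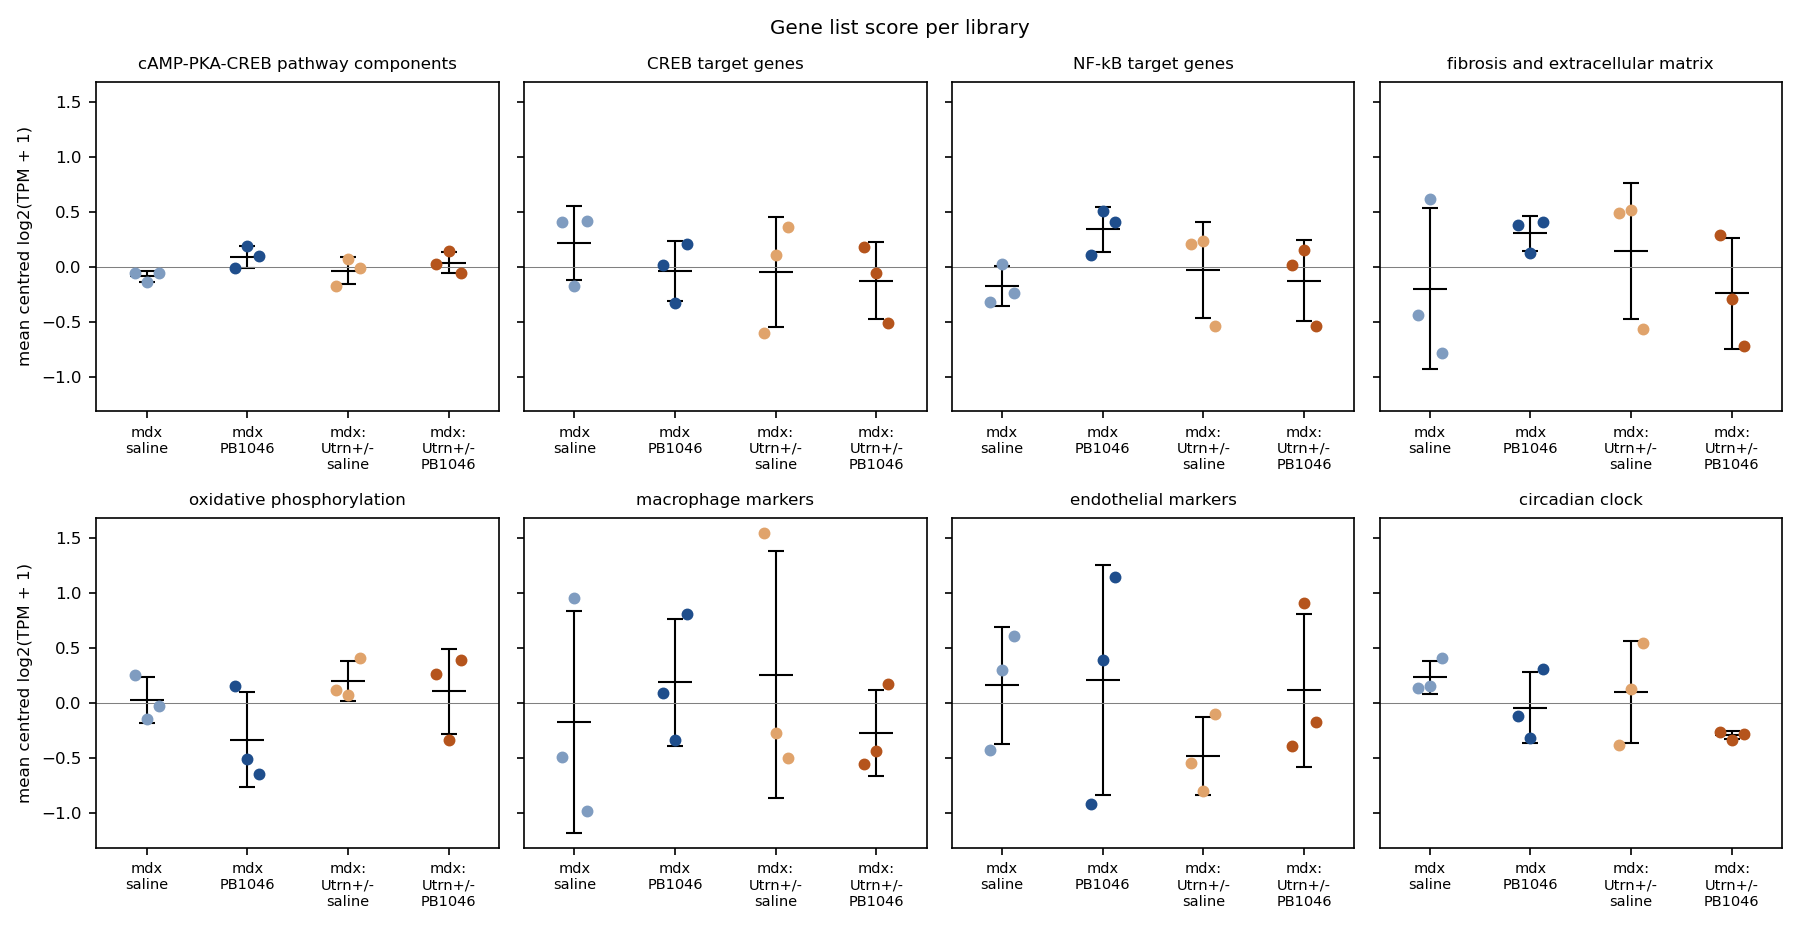
Score of 8 gene lists (mean centred log2(TPM + 1) of the members, y axis) in each library (points) of the 4 groups (x axis), with black bars for mean ± SD of 3 libraries. NF-kB target genes and extracellular matrix genes were highest on average in mdx PB1046, and within groups the scores of single libraries overlapped in most panels.

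In mdx:Utrn+/- saline against mdx saline all 30 fatty acid oxidation genes were higher (median log2 0.40, adjusted p = 9.25e-05). Lipoprotein lipase Lpl was 4101 ± 695 TPM in mdx and 7904 ± 2717 TPM in mdx:Utrn+/- (log2 1.17) and the carnitine palmitoyltransferase Cpt2 141 ± 39.5 and 195 ± 53.2 TPM. All 12 cardiac stress genes were higher (0.66, adjusted p = 0.00179), with skeletal actin Acta1 at 299 ± 406 and 535 ± 398 TPM. Of oxidative stress genes 17 of 18 were higher (0.25, adjusted p = 0.00307), with metallothionein Mt1 at 495 ± 177 and 1117 ± 209 TPM (log2 1.50). Unfolded protein response genes were higher (12 of 15, 0.34, adjusted p = 0.00441), with the chaperone Hspa5 at 314 ± 93.7 and 472 ± 78.7 TPM. Heat shock genes were higher (8 of 10, 0.31, adjusted p = 0.0269), with the co-chaperone Bag3 at 203 ± 26.03 and 303 ± 29.2 TPM and Hsp90aa1 at 122 ± 19.7 and 184 ± 76.6 TPM. Glycolysis genes were higher (16 of 18, 0.29, adjusted p = 0.00450), with lactate dehydrogenase Ldha at 1086 ± 108 and 1448 ± 360 TPM. Sarcomere genes were higher (14 of 16, 0.25, adjusted p = 0.0269), with the light chain Myl3 at 18015 ± 1319 and 24490 ± 3034 TPM. On the lower side were all 15 endothelial markers (-0.59, adjusted p = 9.25e-05), with Kdr at 40.8 ± 14.4 and 15.5 ± 1.89 TPM and the endothelial glycoprotein Emcn at 70.03 ± 24.5 and 30.1 ± 6.96 TPM. Interferon response genes were lower in 24 of 30 (-0.29, adjusted p = 0.000759), with Ifit2 at 12.1 ± 0.871 and 6.07 ± 0.755 TPM. Also lower were 14 of 16 cell dissociation stress genes (-0.43, adjusted p = 0.00179) and 13 of 22 CREB target genes (-0.14, adjusted p = 0.0357). The last 2 lists share Egr1 (96.2 ± 22.7 and 29.8 ± 4.08 TPM), Junb (157 ± 38.5 and 68.5 ± 12.8 TPM) and Fos (163 ± 47.4 and 69.0 ± 33.0 TPM). All 11 calls had an adjusted p of 0.782 with an estimated correlation.

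On the higher side the smallest unadjusted p under saline belonged to Erdr1 (2.54 ± 4.31 and 54.1 ± 35.2 TPM, log2 4.60), Cib3 (0.957 ± 0.339 and 2.55 ± 0.798 TPM) and Wdfy2 (1.06 ± 0.168 and 2.14 ± 0.494 TPM). The actin-binding gene Synpo (22.6 ± 4.76 and 36.9 ± 7.38 TPM, log2 0.95) and the calprotectin subunit S100a9 (1.22 ± 0.913 and 5.16 ± 0.681 TPM) followed. On the lower side were Hspa12a (11.5 ± 2.99 and 4.39 ± 0.608 TPM, log2 -0.96), the Y-linked translation factor Eif2s3y (86.8 ± 7.75 and 40.02 ± 12.6 TPM), and Parp16 (5.54 ± 0.468 and 2.54 ± 0.407 TPM). So were Gkn3 (at most 1 read per library in mdx:Utrn+/- saline) and Mir186 (listed at 0 there). In the dystrophin-glycoprotein complex list, which also holds Utrn, 10 of 15 genes were higher (median 0.24, adjusted p = 0.197), with the caveolin Cav3 at 162 ± 4.94 and 213 ± 43.4 TPM. In the calcium handling list 15 of 21 were higher (0.25, adjusted p = 0.0922), with the junctophilin Jph2 at 176 ± 31.2 and 267 ± 64.3 TPM. Other lists not called were macrophage markers (18 of 18 higher, 0.42, adjusted p = 0.0541), oxidative phosphorylation (27 of 31 higher, 0.18), erythroid (1.28), extracellular matrix (0.32), cell cycle (-0.07) and clock (-0.23). Others were NF-kB pathway components (-0.04), mesothelial (-0.11), cAMP-PKA-CREB components (0.05), atrial (0.05), NF-kB target genes (0.08), smooth muscle (0.12) and fibroblast markers (-0.01). For atrial, smooth muscle and fibroblast markers the mean and the test took the opposite sign of the median.

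No gene passed between genotypes under saline by limma or limma-voom (0 genes each, smallest adjusted p 0.409). At an unadjusted p under 0.05 limma had 531 genes (328 higher, 203 lower) and limma-voom 493, with 640 by chance. With library weights estimated from the residuals (0.35 to 3.44), an alternative chosen after the data were seen, limma called 2071 genes (1168 higher, 903 lower). Of the 11 list calls (7 up, 4 down) 2 (endothelial markers and the unfolded protein response) held in all 12 refits that left out a library and 9 ended at least once. On the first principal component mdx saline had 2 libraries and mdx:Utrn+/- saline none on the side of high endothelial scores. The fatty acid oxidation call ended without mdx saline replicate 2 (adjusted p = 0.0766, range 4.53e-09 to 0.0766) and the cardiac stress call without mdx saline replicate 3 (0.185, range 8.86e-08 to 0.185). The heat shock call ended without mdx:Utrn+/- saline replicate 3 (0.992), mdx saline replicate 2 (0.168) or mdx saline replicate 3 (0.0530, range 3.62e-05 to 0.992). The CREB target call ended without mdx:Utrn+/- saline replicate 1 (0.855), mdx saline replicate 1 (0.277) or mdx saline replicate 3 (0.119, range 0.000657 to 0.855), and with the Rn45s term (0.0516). The sarcomere call ended without mdx:Utrn+/- saline replicate 3 (0.325) or mdx saline replicate 2 (0.0951, range 0.00422 to 0.325). The same libraries ended the interferon call (0.0516 and 0.0951, range 3.64e-06 to 0.0951). The glycolysis (0.0530, range 0.000726 to 0.0530) and oxidative stress calls (0.0530, range 0.000148 to 0.0530) ended without mdx saline replicate 3, and the cell dissociation call without mdx:Utrn+/- saline replicate 1 (0.0574, range 8.38e-05 to 0.0574). The log2 difference across genes went with abundance (rho 0.24) and transcript length (rho -0.21). With these trends removed sarcomere (adjusted p = 0.163) and glycolysis genes (0.0949) had no call and fatty acid oxidation genes had a smaller median of 0.24 (24 of 30 higher, adjusted p = 0.00233, and adjusted p = 0.807 with an estimated correlation). With the endothelial score as a term all 11 calls ended, those of sarcomere (0.857), glycolysis (0.579), fatty acid oxidation (0.579), cardiac stress (0.250), heat shock (0.143), CREB target (0.117), oxidative stress (0.0993), unfolded protein response (0.0509) and cell dissociation genes (0.0509) among them. The interferon list turned upward with it (0.853), and the endothelial list itself was removed by construction.

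With PB1046 all 31 oxidative phosphorylation genes were higher in mdx:Utrn+/- than in mdx (median log2 0.48, adjusted p = 4.73e-14), as were 15 of 16 sarcomere genes (0.32, adjusted p = 7.56e-06) and 16 of 18 glycolysis genes (0.26, adjusted p = 0.000210). The same held for 27 of 30 fatty acid oxidation (0.22, adjusted p = 0.00117), 11 of 12 cardiac stress (0.45, adjusted p = 0.0110), 11 of 15 unfolded protein response (0.13, adjusted p = 0.0110), 8 of 10 heat shock (0.34, adjusted p = 0.0161) and 19 of 21 calcium handling genes (0.21, adjusted p = 0.0223). Lower in mdx:Utrn+/- were 28 of 31 extracellular matrix genes (-0.62, adjusted p = 5.67e-07), 24 of 26 NF-kB target genes (-0.44, adjusted p = 6.69e-07) and all 14 fibroblast markers (-0.62, adjusted p = 2.72e-05). So were 17 of 18 macrophage markers (-0.45, adjusted p = 0.000694), 8 of 9 smooth muscle and pericyte markers (-0.48, adjusted p = 0.000694) and 27 of 30 interferon response (-0.22, adjusted p = 0.00169) genes. Also lower were 5 of 7 atrial (-0.76, adjusted p = 0.00497), 13 of 16 cell cycle (-0.28, adjusted p = 0.00639) and 11 of 16 clock genes (-0.29, adjusted p = 0.0149). The interferon list turned upward without mdx:Utrn+/- PB1046 replicate 1 (0.826, range 7.20e-09 to 0.826), and its call ended without mdx PB1046 replicate 2 (0.676) or 3 (0.255). With an estimated correlation each adjusted p was 0.481 or 0.563. Of the 17 calls (8 up, 9 down), oxidative phosphorylation, extracellular matrix, NF-kB target and sarcomere genes held in all 12 refits that left out a library, and 13 ended at least once.

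This comparison went with abundance across genes more than any other (rho 0.35, and rho -0.20 with transcript length). With both trends removed the median of oxidative phosphorylation genes was 0.14 (adjusted p = 0.00294), and the sarcomere (median 0.07, adjusted p = 0.360), glycolysis (0.07, 0.130) and fatty acid oxidation calls (0.06, 0.220) ended. Extracellular matrix (-0.57, 6.47e-07), NF-kB target (-0.37, 6.47e-07) and macrophage genes (-0.57, 0.000950) kept theirs. With an estimated correlation their adjusted p was 0.654, 0.648 and 0.797, and that of oxidative phosphorylation genes 0.797. On the high endothelial side of the first principal component were 2 mdx PB1046 libraries and 1 of mdx:Utrn+/- PB1046. Scores of oxidative phosphorylation, sarcomere and glycolysis genes ran against it (Pearson r = -0.82, -0.83 and -0.96 over 12 libraries). As a term the endothelial score (mean 0.21 in mdx PB1046, 0.12 in mdx:Utrn+/- PB1046) could hardly move these 17 calls and ended 0. Leaving out mdx PB1046 replicate 3 ended 11 of the calls: fatty acid oxidation (adjusted p = 0.494), calcium handling (0.476), cardiac stress (0.262), heat shock (0.255), clock (0.255), fibroblast (0.223), macrophage (0.218), smooth muscle (0.0762), atrial (0.0675), glycolysis (0.0501) and interferon genes. Without mdx:Utrn+/- PB1046 replicate 3 calcium handling (0.636), unfolded protein response (0.379), cardiac stress (0.251) and fatty acid oxidation calls (0.165) ended. Without mdx:Utrn+/- PB1046 replicate 1 those of heat shock (0.256), calcium handling (0.0722) and cardiac stress (0.0632) ended, and without replicate 2 that of the clock (0.0852). Without mdx PB1046 replicate 1 clock (0.0874) and cell cycle calls (0.0580) ended, and without replicate 2 calcium handling (0.398) and unfolded protein response (0.0562). The ranges reached up from 0.000335 for calcium handling, 8.06e-07 for fatty acid oxidation, 0.000808 for cardiac stress, 0.00280 for the unfolded protein response, 0.00194 for heat shock and 0.000135 for the clock. For macrophage, fibroblast, smooth muscle, atrial, glycolysis and cell cycle lists they reached up from 8.55e-07, 4.06e-09, 2.71e-05, 0.000592, 6.04e-06 and 0.00370. The Rn45s term ended cardiac stress (0.268), calcium handling (0.207), heat shock (0.191), cell cycle (0.131), unfolded protein response (0.0878), atrial (0.0878) and smooth muscle (0.0823) calls.

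Genes with the smallest unadjusted p between genotypes under PB1046 were C2cd4b (0.448 ± 0.146 TPM in mdx and 1.98 ± 0.671 TPM in mdx:Utrn+/-), Spink4 (0.320 ± 0.554 and 3.48 ± 1.87 TPM), Snord104, Mir1839 and AF357399 on the higher side. On the lower side were the glucocorticoid-responsive transcription factor Klf9 (34.2 ± 12.6 and 14.3 ± 4.45 TPM, log2 -0.94), Spsb1 (20.9 ± 2.19 and 11.4 ± 1.06 TPM, log2 -0.60), Mir7670, Mir3069 and Snora52. Of these, Mir1839, AF357399, Mir3069 and Snora52 had at most 4 reads in any library of these groups. The lists not called were NF-kB pathway components (17 of 26 lower, median -0.10, adjusted p = 0.0557), cAMP-PKA-CREB components (21 of 30 lower, -0.10, adjusted p = 0.405) and CREB targets (0.04). Neither were endothelial markers (-0.06), the dystrophin-glycoprotein complex (0.14), cell dissociation stress (-0.13), mesothelial markers (0.01), erythroid markers (-0.02) and oxidative stress (0.05). Mean and test had the opposite sign of the median for CREB targets and oxidative stress. No gene passed by limma or limma-voom (0 genes each, smallest adjusted p 1). At an unadjusted p under 0.05 limma had 214 genes (110 higher, 104 lower) and limma-voom 227, with 640 by chance.

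The PB1046 response of extracellular matrix genes was lower in mdx:Utrn+/- than in mdx for 27 of 31 members (median difference of the log2 changes -0.85, adjusted p = 3.80e-06). So was that of macrophage markers (18 of 18, -0.90, adjusted p = 0.000174), NF-kB target genes (21 of 26, -0.53, adjusted p = 0.000637), fibroblast markers (13 of 14, -0.64, adjusted p = 0.00547) and oxidative stress genes (16 of 18, -0.23, adjusted p = 0.0175). It was higher for oxidative phosphorylation genes (27 of 31, 0.27, adjusted p = 0.000637), endothelial markers (15 of 15, 0.38, adjusted p = 0.00547) and cell dissociation stress genes (10 of 16, 0.22, adjusted p = 0.0210). All 8 had an adjusted p of 0.867 with an estimated correlation. On scores per library an exact permutation test of treatment within genotype (400 relabelings, two-sided) gave p = 0.125 for NF-kB target genes (difference -0.61, 95% interval -1.45 to 0.23) and p = 0.19 for extracellular matrix genes (-0.89, -2.35 to 0.57). Over 10 scores the adjusted p of both was 0.625. The NF-kB target and extracellular matrix calls held in all 12 refits that left out a library and the other 6 ended at least once. The macrophage call ended without mdx:Utrn+/- saline replicate 1 (adjusted p = 0.225, range 7.13e-12 to 0.225). The endothelial call ended without mdx PB1046 replicate 1 (0.931), mdx:Utrn+/- PB1046 replicate 2 (0.438) or mdx saline replicate 3 (0.102, range 1.23e-07 to 0.931). The fibroblast call ended without mdx PB1046 replicate 3 (0.336), mdx:Utrn+/- saline replicate 1 (0.108), mdx saline replicate 3 (0.102) or mdx saline replicate 1 (0.0995, range 2.75e-06 to 0.336). The oxidative phosphorylation call ended without mdx PB1046 replicate 3 (0.112), mdx:Utrn+/- PB1046 replicate 3 (0.0720) or mdx saline replicate 1 (0.0505, range 1.27e-10 to 0.112). The oxidative stress call ended without mdx:Utrn+/- PB1046 replicate 2 (0.184), mdx saline replicates 3 (0.157) or 2 (0.0597), mdx PB1046 replicate 1 (0.0787) or mdx:Utrn+/- saline replicate 1 (0.0776, range 0.000630 to 0.184). The cell dissociation call ended without mdx:Utrn+/- PB1046 replicates 1 (0.299) or 2 (0.184), mdx:Utrn+/- saline replicate 1 (0.226), mdx PB1046 replicates 1 (0.154) or 2 (0.0761), or mdx saline replicates 1 (0.103) or 3 (0.0978, range 2.05e-06 to 0.299). With log2 Rn45s as a term the NF-kB target (0.239), oxidative phosphorylation (0.239) and fibroblast (0.147) calls ended. With the endothelial score as a term the oxidative stress (0.173) and cell dissociation calls (0.194) ended. With the length and abundance trends removed the median of oxidative phosphorylation genes was 0.17 (adjusted p = 0.0122, and adjusted p = 0.837 with an estimated correlation).

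No list call was made for the difference in cAMP-PKA-CREB components (19 of 30 lower, median -0.17, adjusted p = 0.433), CREB targets (13 of 22 higher, 0.13, adjusted p = 0.311) or NF-kB pathway components (17 of 26 lower, -0.12, adjusted p = 0.613). The other lists without a call gave medians of -0.48 (smooth muscle, adjusted p = 0.0512), -0.43 (atrial), -1.36 (erythroid), -0.19 (fatty acid oxidation), 0.12 (sarcomere), -0.22 (cardiac stress) and -0.17 (dystrophin-glycoprotein complex). Further medians were 0.12 (interferon response), -0.19 (unfolded protein response), 0.08 (mesothelial), -0.15 (cell cycle), -0.04 (clock), -0.30 (heat shock), -0.04 (glycolysis, test upward) and 0.00 (calcium handling, mean negative). Hspa12a was 11.5 ± 2.99 and 9.15 ± 2.41 TPM in mdx saline and PB1046. In mdx:Utrn+/- it was 4.39 ± 0.608 and 9.85 ± 2.35 TPM (difference of log2 changes 1.26). Grip2 (2.16), Zscan18 (1.00), Eif2s3y (1.10) and Mir186 (1.59) stood on the same side. The transcription factor Foxo3 was 3.60 ± 1.17 and 7.87 ± 1.70 TPM in mdx and 4.93 ± 0.238 and 3.76 ± 1.35 TPM in mdx:Utrn+/- (-1.35). Midn (-1.07), Spsb1 (-0.94), Usp17la (-1.82) and Mir6914 (-2.28) stood with it. Mir186 rested on at most 3 and Mir6914 on at most 5 reads in any library. No gene passed by limma or limma-voom (0 genes each, smallest adjusted p 1.00). At an unadjusted p under 0.05 limma had 292 genes (130 higher, 162 lower) and limma-voom 279, with 640 by chance. Without mdx:Utrn+/- saline replicate 3 limma called 1 gene, Tmem181b-ps (adjusted p = 0.0283), which the naming rule did not pick and which is named after its values were seen.

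**Figure D4:**
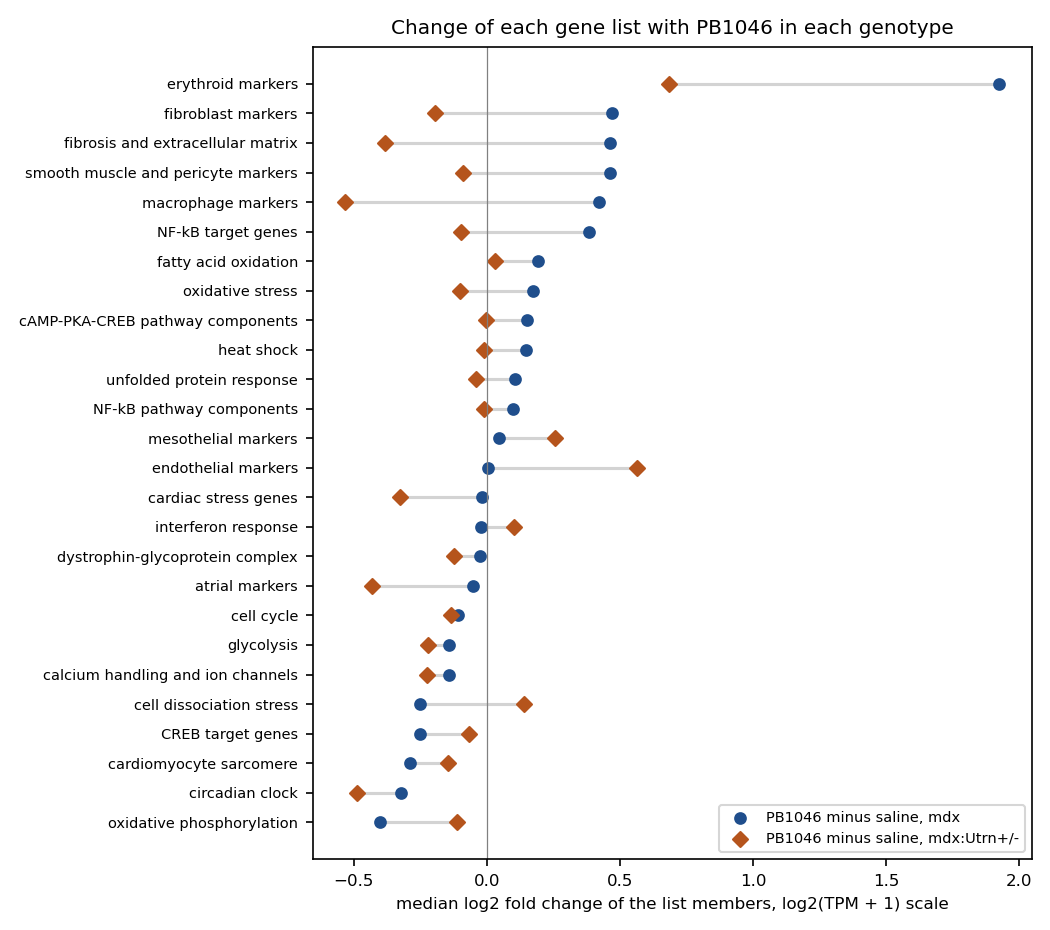
Median log2 change with PB1046 (x axis) of the members of each tested list (y axis) in mdx (blue circles) and mdx:Utrn+/- (brown diamonds), each from 3 against 3 libraries. Extracellular matrix genes had medians of 0.46 and -0.38 and macrophage markers 0.42 and -0.53 in mdx and mdx:Utrn+/-.

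Averaged over both genotypes, 29 of 31 oxidative phosphorylation genes were lower with PB1046 (median log2 -0.22, adjusted p = 7.30e-07), as were 16 of 16 sarcomere (-0.23, adjusted p = 0.000118) and 16 of 18 glycolysis genes (-0.26, adjusted p = 0.000246). Also lower were 13 of 16 clock (-0.41, adjusted p = 0.000361), 17 of 21 calcium handling (-0.19, adjusted p = 0.00785) and 14 of 16 cell cycle genes (-0.12, adjusted p = 0.0460). Higher were erythroid markers (5 of 5, 1.32, adjusted p = 0.000246), NF-kB target genes (22 of 26, 0.24, adjusted p = 0.00313) and endothelial markers (14 of 15, 0.29, adjusted p = 0.00313). So were cAMP-PKA-CREB components (22 of 30, 0.09, adjusted p = 0.0292) and smooth muscle and pericyte markers (8 of 9, 0.17, adjusted p = 0.0450). With an estimated correlation the adjusted p of these 11 lists was 0.768 or 0.820. The remaining lists gave medians of 0.09 (fatty acid oxidation), 0.12 (mesothelial), 0.08 (NF-kB pathway components), 0.20 (fibroblast), 0.06 (interferon response), -0.12 (CREB targets), -0.17 (cardiac stress), -0.29 (atrial) and 0.11 (extracellular matrix). The last were -0.04 (macrophage), -0.11 (dystrophin-glycoprotein complex), 0.07 (heat shock), -0.07 (cell dissociation stress), 0.04 (oxidative stress) and 0.03 (unfolded protein response), the last pair with mean and test negative.

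In the clock list 7 genes had an unadjusted p under 0.05 in this average, 5 passed when adjusted over the list alone and 0 when adjusted over all genes. Dbp (-1.23), Per3 (-0.96) and Tef (-0.72), whose transcription the clock activators drive, were lower on the log2 scale and Arntl (1.19) was higher. Genes with the smallest unadjusted p were Spata5l1 (log2 0.62), the zinc finger gene Zbtb12 (0.52), the secretoglobin Scgb3a1 (0.82), Mir7028 (1.07) and Mir5129 (1.45) on the higher side. On the lower side were Klhl38 (-0.74), C8g (-0.67), the ribonuclease H subunit Rnaseh2c (-0.44), Snora23 (-0.93) and Mir186 (-0.80). Of these, Mir7028 rested on at most 2 reads in any library, Mir5129 on at most 7, and Snora23 and Mir186 on at most 3. No gene passed by limma or limma-voom (0 genes each, smallest adjusted p 1.00). At an unadjusted p under 0.05 limma had 329 genes (170 higher, 159 lower) and limma-voom 342, with 640 by chance. Of the 11 list calls (5 up, 6 down) 5 (oxidative phosphorylation, sarcomere, glycolysis, clock and erythroid) held in all 12 refits that left out a library. The NF-kB target call ended without mdx saline replicate 1 (adjusted p = 0.0541), mdx:Utrn+/- saline replicate 3 (0.257) or mdx:Utrn+/- PB1046 replicate 2 (0.0899, range 4.24e-05 to 0.257). The cAMP-PKA-CREB call ended without mdx saline replicate 2 (0.0661), mdx PB1046 replicate 2 (0.0533), mdx:Utrn+/- saline replicate 1 (0.190) or mdx:Utrn+/- PB1046 replicate 2 (0.0548, range 0.00822 to 0.190). The endothelial call ended without mdx PB1046 replicate 3 (0.441), mdx:Utrn+/- PB1046 replicate 2 (0.281), mdx saline replicate 1 (0.260) or mdx:Utrn+/- saline replicate 2 (0.0511, range 2.46e-07 to 0.441). The calcium handling call ended without mdx saline replicate 1 (0.313), mdx:Utrn+/- PB1046 replicate 2 (0.179), mdx PB1046 replicate 3 (0.136) or mdx:Utrn+/- saline replicate 2 (0.0511, range 0.000158 to 0.313). The smooth muscle call ended without mdx:Utrn+/- saline replicate 3 (0.512), mdx PB1046 replicate 3 (0.410), mdx saline replicates 1 (0.236) or 3 (0.103), or mdx:Utrn+/- PB1046 replicates 1 (0.170) or 2 (0.0845, range 0.00239 to 0.512), and with the Rn45s term (0.312). The cell cycle call ended without mdx:Utrn+/- saline replicates 1 (0.803) or 2 (0.0511), mdx saline replicate 2 (0.686), mdx PB1046 replicates 1 (0.126) or 2 (0.0533), or mdx:Utrn+/- PB1046 replicates 1 (0.0685) or 3 (0.123, range 0.000953 to 0.803). With the length and abundance trends removed the oxidative phosphorylation (median -0.04, adjusted p = 0.439) and sarcomere calls (-0.08, 0.155) ended, and the median of glycolysis genes went from -0.26 to -0.12 (adjusted p = 0.01003, and adjusted p = 0.711 with an estimated correlation). With the endothelial score as a term the calls of glycolysis (adjusted p = 0.0601), NF-kB target (0.0794), cell cycle (0.106), smooth muscle (0.214) and calcium handling genes (0.518) ended, and that of endothelial markers by construction.

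Across the 12798 genes the PB1046 log2 changes in mdx and in mdx:Utrn+/- showed no relation beyond chance (Pearson r = -0.04, Spearman rho = -0.01 across genes, which are not independent replicates). The sign was the same in 51.1% of genes. Of the 400 arrangements of libraries within genotypes 364 gave an r as large (permutation p = 0.91), with a median size of r of 0.22. At 3 libraries per group the median 95% interval of a log2 change reached 0.556 to either side for genes with an average log2 level of at least 1. The deposited comparisons of the authors, from their own edgeR fit, also held 0 genes at a false discovery rate under 0.05 in each of 6 pairs of groups. They had 755 genes at a p-value under 0.05 for PB1046 in mdx, 586 for PB1046 in mdx:Utrn+/-, 862 between genotypes under saline and 501 under PB1046.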

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

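The list tests and the counts of splits below were planned in advance. The tests of a lower share of cardiomyocytes (the score test with it), of RNA of endothelial cells, of the length and abundance trend in the difference between genotypes, and the fits with Rn45s or the first component of the residuals as a term were chosen only after the result was seen. What set these lists apart is that their PB1046 response differed between mdx and mdx:Utrn+/- by limma camera at its preset correlation. With an estimated correlation 0 of the 8 were called.

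Extracellular matrix genes (adjusted p = 3.80e-06), macrophage markers (0.000174) and fibroblast markers (0.00547) had a lower PB1046 response in mdx:Utrn+/- than in mdx, and endothelial markers (0.00547) a higher one. A lower share of cardiomyocytes in some libraries would move the markers of all other cell types alike. Macrophage (median -0.90, SD over members 0.28) and endothelial markers (0.38, SD 0.34) moved apart by -1.27. Their scores showed no relation over the 12 libraries (Pearson r = -0.03, permutation p = 0.925). But the macrophage minus endothelial score moved by -1.44 (95% interval -4.26 to 1.38, exact permutation p = 0.26), within the spread between libraries, so this cannot decide. A different mix of the other cell types may lie behind the pattern, and a fit with the first component of the residuals as a term, in which 4 of 4 list calls were made, cannot test it because that term leaves every group difference where it was (largest shift of a log2 change 0). Chance cannot be excluded, with a camera p as small in 26, 32, 28 and 43 of 100 splits for the matrix, macrophage, fibroblast and endothelial lists (lowest p in another split 1.81e-16, 6.45e-22, 1.92e-12 and 4.31e-14), and a different response in the genotypes, which the design names, stays open.

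Oxidative phosphorylation genes were lower with PB1046 in mdx (median log2 -0.40), and their response was higher in mdx:Utrn+/- (0.27, adjusted p = 0.000637), a call that left-out libraries (3 of 12) and the Rn45s term (0.239) ended. With the trends of the log2 change over gene length and abundance removed, the median in mdx was -0.12 (standard error over members 0.0273), under the bound of -0.20 in size set for this explanation, so a bias of length or abundance may account for most of that shift, and what was left passed at the preset correlation (adjusted p = 0.0174) and not with an estimated one (0.754). For the difference between genotypes the same removal left 0.17 (standard error 0.0407, adjusted p = 0.0122, and 0.837 with an estimated correlation), within 1 standard error of its bound of 0.14, and so cannot decide there. Dilution by RNA of endothelial cells would need endothelial markers to rise, and their median in mdx was level (0.00397, SD over members 0.263). But list scores of -0.51 and -0.64 in mdx PB1046 came with endothelial scores 0.39 and 1.15, and 0.16 with -0.92, so this cannot decide. The endothelial score as a term (median -0.39, shift 0.0120) tests nothing there. In the difference both lists were higher, against what dilution gives, and with that term the median was 0.42 (adjusted p = 1.22e-09). For the difference between genotypes 38 of 100 splits gave a camera p as small (lowest in another split 2.09e-15), so chance cannot be excluded. RNA of other cell types and a response to PB1046 in mdx stay open and were not tested apart from these.

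NF-kB target (adjusted p = 0.000637, but 0.239 with the Rn45s term), oxidative stress (0.0175) and cell dissociation stress genes (0.0210) differed in their response. A camera p as small came in 18, 15 and 38 of 100 splits, so chance cannot be excluded.

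For the 4 comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05. PB1046 in mdx had 0 genes (highest of the other splits 1; as many or more in 10 of 10 splits, the real one included) and 12 lists (17; 3 of 10), PB1046 in mdx:Utrn+/- 0 genes (1; 10 of 10) and 5 lists (16; 10 of 10). The genotype comparison had 0 genes (6; 10 of 10) and 11 lists (15; 5 of 10) under saline, and 0 genes (1086; 10 of 10) and 17 lists (18; 2 of 10) under PB1046. The split with 1086 genes set mdx PB1046 replicates 2 and 3 and mdx:Utrn+/- PB1046 replicate 2 against the other 3 PB1046 libraries, the sides that they take on the first principal component, and so points to a structure of the samples that the groups do not follow. Among 100 splits, the response difference between genotypes had 0 genes (309; 100 of 100) and 8 lists (19; 77 of 100), and the average PB1046 response 0 genes (309; 100 of 100) and 11 lists (21; 56 of 100), so chance cannot be excluded for any of these counts, and 309 genes again point to a structure of the samples.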

How the results depend on the processing

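All limits here are for 12 libraries, 31 alternative settings of which 12 left out a library, and the threshold of 0.05. The tests with TPM unscaled, a pseudocount of 0.1, library weights, without small RNA entries, or with terms for Rn45s, the endothelial score or the first residual component were chosen only after the result was seen. Of 4031 values of the genes in the text under these settings 3993 kept their direction and side, 28 passed (all with library weights) and 10 reversed. Over all 802 pairs of gene and contrast that the naming rule allows, 22511 of 22933 values kept both and 359 reversed, in 136 pairs with a median size of the log2 change of 0.11. Of 2168 list values 1834 kept both, 286 lost the call, 13 gained it and 35 reversed. Genes were called in 2 settings only. Library weights, which leaned on 1 library in each saline group, gave 2071 between genotypes under saline. Leaving out mdx:Utrn+/- saline replicate 3 gave 1 for the response difference. Vipr1 and Vipr2 did not pass in the fit without a filter. A term for sex and a fit without mitochondrial genes were not run, since all libraries were male by expression and the table lists no such gene. The planned count models were not run: the deposited unit is TPM, and reads recovered from it were given to limma-voom only. The replicate block called 0 genes, and replicate numbers did not pair the libraries.

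The cause was not tested for the values that follow, which are adjusted p of list tests unless named otherwise. CREB target genes for PB1046 in mdx:Utrn+/- reversed with median-of-ratios (0.983) and upper-quartile scaling (0.944), only the 2 groups (0.846), TPM unscaled (0.580) and the endothelial term (0.811). In mdx they passed with only the 2 groups (0.0345), a threshold of 0.1 (0.0883) and TPM unscaled (0.0137). NF-kB target genes in mdx:Utrn+/- reversed with limma-voom (0.914) and the Rn45s term (0.634) and passed with library weights (0.0484). NF-kB components passed in mdx with the term for the 3 lowest library numbers (0.0359), and reversed in mdx:Utrn+/- with library weights (0.984) and the endothelial term (0.480) and for the response difference with the Rn45s term (0.827). The cAMP list lost its call in mdx with the Rn45s term (0.0614) and reversed in mdx:Utrn+/- with library weights (0.920). The response difference of NF-kB targets was lost with the Rn45s term (0.239). With an estimated correlation 0 lists were called in mdx, in mdx:Utrn+/- and for the response difference (NF-kB targets and cAMP list in mdx 0.743, NF-kB targets for the difference 0.867). The endothelial term reversed endothelial markers in mdx:Utrn+/- (0.811) and in the average (0.596), by its construction, and the interferon list between genotypes under saline (0.853). Lists called for PB1046 in mdx:Utrn+/- numbered 10 at a threshold of 0.1, 9 with TPM unscaled and 8 with the Rn45s or residual component term, and in mdx 7 with the Rn45s term. For PB1046 in mdx:Utrn+/- the log2 change of Dmd was 0.0538 with TPM unscaled, and that of Utrn -0.0710 with library weights and -0.0430 with the endothelial term.

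Leaving out each library in turn gave these lowest and highest values. In mdx: cAMP list 0.0210 and 0.164, CREB target genes 0.00182 and 0.574, NF-kB components 0.0122 and 0.768, fatty acid oxidation 5.34e-06 and 0.858, macrophage markers 3.84e-09 and 0.868. In mdx:Utrn+/-: CREB target genes 0.0294 and 0.991, NF-kB targets 0.0245 and 0.875, NF-kB components 0.136 and 0.811, cAMP list 0.107 and 0.887, macrophage markers 1.32e-05 and 0.474, lists called 5 and 13. Response difference: NF-kB components 0.102 and 0.978, CREB targets 0.0197 and 0.719, lists called 4 and 11, genes 0 and 1. Interferon list between genotypes under PB1046: 7.20e-09 and 0.826. Log2 change of Utrn with PB1046: -0.00312 and 0.51 in mdx, -0.00475 and 0.37 in mdx:Utrn+/-. Log2 difference of Dmd: -0.48 and 0.16 with PB1046 in mdx:Utrn+/-, -0.39 and 0.26 between genotypes under saline, -0.20 and 0.0485 under PB1046.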

Other observations

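Of the tests below, that of ribosomal RNA carry-over was chosen only after the result was seen.

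Marker lists of other cells that were too small for a list test gave these values, with 0 genes adjusted over all genes in limma. The calprotectin genes S100a8 (0.905 ± 0.253, 3.17 ± 2.76, 4.05 ± 2.01 and 4.35 ± 3.28 TPM in mdx saline, mdx PB1046, mdx:Utrn+/- saline and mdx:Utrn+/- PB1046) and S100a9 (1.22 ± 0.913, 3.53 ± 2.68, 5.16 ± 0.681 and 5.81 ± 4.55 TPM) are neutrophil markers, and S100a8 rested on 0 to 27 reads per library. Of the 4 measured members of that list 4 were higher in mdx:Utrn+/- under saline (median log2 0.99), with 2 at an unadjusted p under 0.05 that also passed when adjusted over the list alone. Lymphocyte markers (3 measured) had median log2 changes with PB1046 of 0.32 in mdx and -0.20 in mdx:Utrn+/-, neutrophil markers 0.38 and -0.22. The single measured adipocyte marker gave 0.14 and -0.59, the single Schwann cell marker -0.01 and 0.20.

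Skeletal muscle markers, 4 of them measured, had median log2 changes of -0.53 in mdx and -0.47 in mdx:Utrn+/-, and 3 passed in the average over genotypes when adjusted over the list alone (0 over all genes). The fast troponin Tnnt3 was 1.95 ± 1.66, 0.470 ± 0.188, 0.984 ± 0.194 and 0.446 ± 0.180 TPM in mdx saline, mdx PB1046, mdx:Utrn+/- saline and mdx:Utrn+/- PB1046. The fast light chain Mylpf, on 2 to 29 reads per library, was 2.12 ± 0.946, 2.81 ± 0.417, 0.893 ± 0.331 and 2.32 ± 0.259 TPM. In the sex-linked list, with a median log2 difference between genotypes of -0.14 under saline, 1 gene, Eif2s3y, passed when adjusted over the list alone.

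The ribosomal precursor entry Rn45s took 0.104% to 4.21% of the TPM of a library, a 40.5-fold range, and was higher in shallower libraries (Pearson r = -0.90 with log2 reads, permutation p = 6e-05, Spearman rho = -0.92, permutation p = 0.00013, r = -0.88 without the 2 libraries farthest from the median, r = -0.92 after the group means were taken out). Lars2 followed Rn45s (r = 0.999, permutation p = 1e-05, the smallest they can give; rho = 0.98; r = 0.998 without the 2 farthest). Adjusted over the 3 relations the p were 6e-05 and 3e-05.

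Adcyap1r1 was higher with PB1046 in mdx, 2.23 ± 1.05 and 6.61 ± 0.92 TPM, without passing in limma. Ribosomal RNA carry-over that differs between libraries is a candidate explanation: after the group means were taken out, r of Adcyap1r1 with Rn45s was 0.92 on TPM without scaling factors. On scaled values it was 0.887, higher than in 99.4% of the 12798 genes, and 52 other genes had an r of at least 0.9. Reads shared with ribosomal RNA were looked for as words of 31 bases, and Adcyap1r1 shared 0 with the 47703 bases searched. Lars2, which follows Rn45s, also shared 0, so the search cannot show the link, and its bound, set in advance, was wrong to count 0 words against it. A response to PB1046 stays open, since depth, Rn45s and treatment cannot be parted in 3 libraries per group.

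The lower Utrn level in mdx:Utrn+/- was set against its neighbours on chromosome 10. The 10 nearest tested genes on each side had a median log2 difference of -0.0281 (range -0.28 to 0.67) where Utrn had -0.64, which argues against a difference shared by the region.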
